A study of Mus musculus with 30 samples.

How the data were processed

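RNA was measured by sequencing in postnatal mouse testis cells enriched for THY1 or KIT with magnetic beads or sorted for GFP. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into directional libraries. CASAVA, TopHat2 2.0.9 and Cufflinks 2.1.1 and the mouse genome build mm9 are named in the submitters' processing notes, which give no order of steps and no annotation. The authors deposited FPKM, fragment counts normalised for transcript length and library size, in 1 table of 20889 gene symbols and 11 columns with 1 value per group. Of the 16 RNA libraries in the labels, 2 stand behind each of 5 columns and 1 behind each of the other 6; how replicates were combined is not stated. The 75th percentile over all 20889 genes lay between 17.2 and 18.2 FPKM in every column, and whether the authors scaled the libraries to each other is not stated. The 8 bisulfite and the 6 chromatin immunoprecipitation and input samples of the 30 samples of the series were not analysed here.

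Read depth is not in the deposited FPKM values. A relative depth was read from genes under 0.05 FPKM, where values fall in steps that stand for whole fragments, a bound picked after looking at the data. Relative to P14 THY1, a step was worth 1.17 times in P0 THY1, 2.03 times in P0 OCT4-GFP, 1.01 times in P7 KIT, 1.72 times in P7 VASA THY1, 1.17 times in P7 OCT4-GFP, 1.04 times in P7 ID4-GFP, 0.959 times in P12 THY1, 1.27 times in P12 KIT and 1.72 times in P14 KIT. In P7 THY1 it was worth 3.68 times, at 14.8% of 237 genes, and other bounds gave a value smaller by a doubling in some pairs, so it is uncertain by a whole-number factor. A larger step means fewer fragments behind a value, so low values are least precise in P7 THY1, if that step holds. No interval could be given without counts.

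From the deposited FPKM, log2(FPKM + 1) and its differences between columns were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. A gene was counted as different at 4-fold or more on that scale, a log2 difference of at least 2, with FPKM of 5 or more in the higher column. Lists, correlations and principal components used the 14200 genes with FPKM of 1 or more in at least 2 columns; 1401 genes were at 0 in every column. Folds against a column at 0 are not given. There were 27 gene lists for germ cell stages, imprinting, signalling, metabolism and the other cell types of the testis. The 25 lists with 5 or more kept members were described by the median difference and its percentile among 10000 random lists of like size, drawn within 20 bins of mean expression, with 2.5 and 97.5 as bounds of the central 95%. For lists of randomly drawn genes 1.25 of 25 fall outside. Over the 13 planned comparisons 186 of 325 list medians did. Members of one list can vary together, so 1.25 is not the rate for such lists without a group difference. The counts of lists outside are therefore descriptive.

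The size rule, the lists, the comparisons and the rule for naming genes were fixed before the data were examined, except 3 comparisons within GFP columns or KIT columns over time, which were added afterwards. A test with limma and camera was also planned for groups with 2 libraries, and was not run because the table holds 1 value per group; the planned size rule for single libraries was used throughout in its place. The rule names the sort markers Thy1, Kit, Pou5f1, Id4 and Ddx4, the 10 genes with the largest differences in each direction under the size rule, 12 imprinted genes, and up to 4 members of each list with a counted member or a median outside the central range. These 4 were to be taken by p, and were taken by size of difference among members with FPKM of 5 or more in a compared column in its place. Sycp3 at P12, its values in the plot of germ cell genes with those of the other genes there, and the genes of the histone, spermatid, blood and immune observations were chosen after their values were seen.

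Gene symbols were used as the table gives them. Of 20889 symbols, 18718 are current symbols in the gene name tables, whose assembly is GRCm38.p6 and which were used for names only, and 20726 are current symbols or synonyms. In the lists 8 symbols were matched through a synonym. Members of gene families that could share reads, among them histone, globin, Hsd3b and Hspa1 genes, have uncertain values.

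The calculation was tested on simulated data made from the real values of the second column of a comparison. Independent noise of 0.3 (SD, log2) was added, a set value that was not estimated from the data. For P7 KIT against P7 THY1, over 20889 genes, 100% of 8-fold and 0% of 2.5-fold changes passed the size rule and 0 unchanged genes did. For P14 THY1 against P12 THY1 the shares were 100% and 2%, with 0 unchanged genes. At this noise an unchanged gene can hardly reach 4-fold, so the 0 was fixed by the setting and gives no rate of false calls in these data. Of 200 unchanged lists of randomly drawn genes 2.5% and 4% in the respective comparison fell outside the central range over 14200 genes, and 100% of lists raised 2-fold did. Genes in these simulated lists did not vary together, so they give no error rate for the gene lists used here. Alternatives tried were a pseudocount of 0.1, quantile normalization, upper-quartile scaling, an 8-fold rule and a stricter expression minimum. Leaving out genes listed at 0, leaving out the minimum of 5 FPKM and exchanging columns were added after seeing the data.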

Results

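RNA was measured in testis cells of C57BL/6 mice at postnatal days 0, 7, 12 and 14, written P0 to P14. Cells were enriched with magnetic beads for THY1, a surface protein of undifferentiated spermatogonia, or for KIT, the receptor of differentiating spermatogonia. Other cells were sorted by fluorescence from mice whose GFP reports OCT4 or ID4 in early germ cells, and 1 library carries the label P7 VASA THY1, whereas the protocol names VASA-GFP cells at P0 only; it was used as labelled, so its age is uncertain. The table held 11 groups: P0 THY1, P7 THY1, P7 KIT, P12 THY1 and P12 KIT stood for 2 libraries each, and P0 OCT4-GFP, P7 OCT4-GFP, P7 ID4-GFP, P7 VASA THY1, P14 THY1 and P14 KIT for 1 library each. Each group had 1 value per gene, so no difference has a replicate check, no test was run between groups, and every value describes these libraries alone. Read depth is unknown. Differences are of log2(FPKM + 1), a scale that understates the change of genes at low level, and genes were counted at a 4-fold difference or more with FPKM of 5 or more in the higher group. Each gene list is given by its median difference and by the percentile of that median among 10000 random lists of like size and expression, as median and percentile in brackets. Paired levels are given with the later age, or the KIT, GFP-sorted or VASA cells, first.

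All columns held germ cell transcripts, and the columns differed in transcripts of other testis cells. Ddx4, which encodes the germ cell helicase VASA, stood between 65.0 FPKM in P0 THY1 and 248 FPKM in P14 THY1. Kit was higher in each KIT column (78.9, 72.5 and 103 FPKM at P7, P12 and P14) than in the THY1 column of its age (21.3, 15.4 and 24.1 FPKM). Thy1 itself stood at 18.3 FPKM in P0 THY1 but at 1.64, 1.17 and 1.20 FPKM in the later THY1 columns, against 0.592, 0.386 and 0.216 FPKM in the KIT columns. Pou5f1, which encodes OCT4, stood at 37.3 and 29.2 FPKM in the P0 and P7 OCT4-GFP columns and at 21.0 FPKM in P7 THY1. Id4 stood at 27.7 FPKM in P7 ID4-GFP and at 29.6 FPKM in P7 THY1. Fibroblast and stroma markers had a median of 249 FPKM in P0 THY1 and 1.62 FPKM in P7 ID4-GFP, the highest and the lowest of the 11 columns. Over 14200 expressed genes, 8 of the 11 columns had their highest correlation with a column of the same age; Pearson's r over all 55 pairs ran from 0.717 to 0.981, across genes, which are not independent replicates. The first principal component held 37.0% of the variance and had P0 THY1 at one end and P7 ID4-GFP at the other, and the second held 23.7% and set P14 THY1 and P14 KIT apart.

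**Figure D1:**
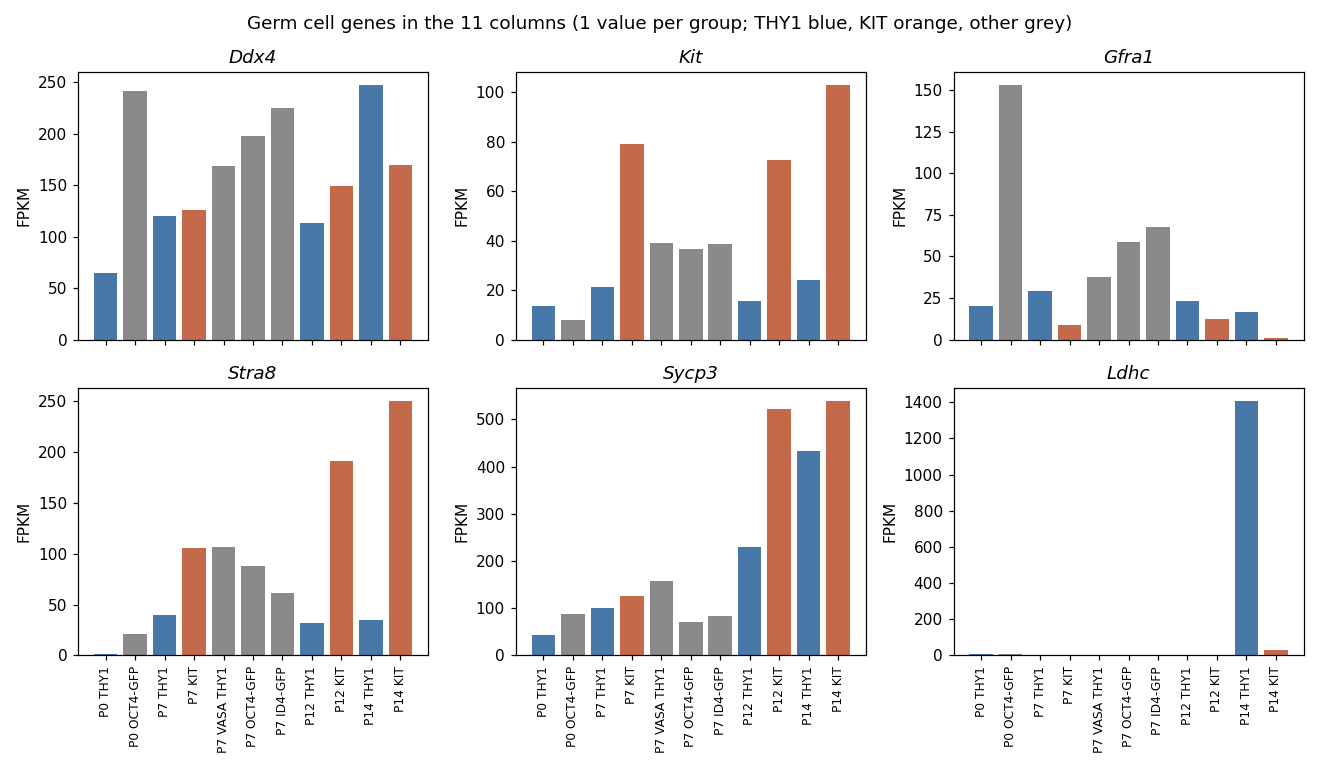
FPKM (vertical axis) of 6 germ cell genes in the 11 columns (horizontal axis), 1 bar per column, THY1 columns in blue, KIT columns in orange and the others in grey. Kit and Stra8 are higher in each KIT column than in the THY1 column of its age, Gfra1 is highest in P0 OCT4-GFP (153 FPKM), Sycp3 is higher at P12 and P14 than before, and Ldhc stands at 1409 FPKM in P14 THY1.

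The comparison of KIT with THY1 cells at P7 asks how differentiating spermatogonia differ from the population that contains the stem cells. Genes of stem cell self-renewal were lower in KIT cells: 9 of 18 list members were at least 2-fold lower and none was 2-fold higher (median -1.13, percentile 0). Among them were Ret and Gfra1, which form the receptor for the niche factor GDNF, at 10.8 against 39.8 FPKM and 8.49 against 29.0 FPKM, and the signalling genes Spry4 (difference -1.65) and Egr4 (-1.38). Immediate early and heat shock genes, which respond to signals and to handling, were lower beside them (median -0.46, percentile 0.02). Genes of differentiating spermatogonia were higher, 8 of 15 by 2-fold or more (median 1.04, percentile 100), with Dmrtb1, a regulator of the entry into meiosis, at 42.7 against 5.49 FPKM, and Lmo1 (1.99), Esx1 (1.85) and Kit (1.84) beside it. Kit, the marker of the selection, is among the 8. Stra8, a retinoic acid target needed for meiosis, stood at 106 against 39.7 FPKM, and the retinoic acid list was higher as a whole (median 0.40, percentile 99.9).

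Leydig cell genes had the largest median difference of the 25 lists at P7: 8 of 12 were at least 2-fold higher in KIT cells and 5 at least 4-fold (median 1.48, percentile 100). The steroid enzyme genes Cyp17a1 and Hsd3b1 stood at 245 against 8.46 FPKM and 324 against 11.8 FPKM, the hormone gene Insl3 at 258 against 18.3 FPKM and the hormone receptor gene Lhcgr at 11.6 against 0.409 FPKM; Hsd3b1 may share reads with its close copies, so its level is uncertain. Sertoli markers (median -0.60, percentile 0), peritubular myoid markers (median -0.89, percentile 0) and macrophage markers (median -0.79, percentile 0) were lower. The spermatid genes Prm1 and Prm2 were listed at 0 in KIT cells and stood at 101 and 29.7 FPKM in THY1 cells. Prm1 was also listed at 0 in P7 VASA THY1, P7 ID4-GFP and P12 THY1 and stood at 1.06 FPKM in P7 OCT4-GFP. Its level in P7 THY1 is thus not shared by the other P7 columns or by P12 THY1, and its source was not tested. By the size rule 75 genes differed, 31 higher and 44 lower in KIT cells. Of 25 lists 17 had a median outside the central 95% of random lists, against 1.25 for lists of randomly drawn genes. With the P7 VASA THY1 library in place of P7 THY1, an alternative chosen after seeing the data, 205 genes were higher and 43 lower in KIT cells, 248 in all, of which 32 were among the 75. The differentiating and self-renewal differences were small against that library. Median levels in P7 KIT against P7 VASA THY1 were 42.9 against 47.1 FPKM for the differentiating list. For the self-renewal list they were 8.22 against 9.14 FPKM. Stra8 stood at 106 against 107 FPKM and Dmrtb1 at 42.7 against 41.2 FPKM, whereas Leydig markers stood at 49.9 against 1.54 FPKM.

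At P12 the same comparison showed genes of meiosis and of differentiating spermatogonia at higher level in KIT cells. Of 35 meiotic prophase genes 26 were at least 2-fold higher and none was 2-fold lower (median 1.28, percentile 100). Prdm9, which places meiotic recombination sites, stood at 31.5 against 4.33 FPKM, Mei1, needed for meiotic DNA breaks, at 22.3 against 4.32 FPKM, and Sycp3, of the synaptonemal complex, at 523 against 229 FPKM. The differentiating list (median 1.05, percentile 100) had 4 of 15 members 4-fold higher: Prdm9, Stra8 (192 against 32.0 FPKM), Esx1 (20.5 against 3.35 FPKM) and Kit. Kit was the marker of the selection, and Prdm9 is also in the meiotic prophase list. Cell cycle genes were higher as a group (median 0.63, percentile 100), with Rrm2 (1.93), Mki67 (1.49), Bub1 (1.40) and Top2a (1.38) in front, and Ctcfl, a germ cell relative of the insulator protein gene Ctcf, stood at 10.1 against 1.49 FPKM.

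Self-renewal genes were lower in P12 KIT cells, 3 of 18 by 2-fold or more (median -0.70, percentile 0), led by Egr4 (-1.19), Dusp6 (-1.17) and Ret (-1.04), and so were immediate early and heat shock genes (median -0.88, percentile 0). Glycolysis genes were lower (median -0.73, percentile 0), with Ldha at 20.2 against 45.6 FPKM. Markers of other cells went both ways: Sertoli markers were lower (13 of 17 by 2-fold or more; median -1.33, percentile 0), as were peritubular myoid (median -1.69, percentile 0), fibroblast (median -1.14, percentile 0) and macrophage markers (median -1.74, percentile 0), whereas Leydig markers were higher (median 0.69, percentile 99.99). Inha, a Sertoli hormone subunit gene, stood at 40.2 against 124 FPKM and the smooth muscle gene Acta2 at 27.2 against 165 FPKM. The size rule counted 50 genes, 29 higher and 21 lower in KIT cells, and 92 with a pseudocount of 0.1, and 15 of 25 lists stood outside the central range.

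The difference between those comparisons asks whether the KIT to THY1 contrast changed from P7 to P12. Meiotic prophase genes had a larger KIT excess at P12 (median 0.90, percentile 100), with Tex15, needed for meiotic DNA repair (1.95), Prdm9 (1.86) and Msh5, a meiotic crossover gene (1.78), and cell cycle genes did too (median 0.45, percentile 100). Leydig genes had a smaller KIT excess at P12 (median -1.31, percentile 0), with Hsd3b1 (-2.88), Cyp17a1 (-2.34) and Nr5a1 (-2.49). The KIT minus THY1 difference was also lower at P12 for fibroblast (median -1.10, percentile 0), peritubular myoid (median -0.96, percentile 0.01) and macrophage markers (median -0.81, percentile 0.04), whose medians at P7 were 0.01, -0.89 and -0.79. By the size rule 92 genes differed, 39 of them with a higher and 53 with a lower KIT minus THY1 difference at P12, and 16 of the former were listed at 0 in at least 1 of the 4 columns. With the P7 VASA THY1 library in place of P7 THY1 the count was 652 (105 higher and 547 lower), and with a pseudocount of 0.1 it was 160.

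At P14, with 1 library on each side, THY1 cells held more transcripts of the self-renewal list and of the late meiotic and spermatid list than KIT cells. The excess did not extend to the spermatid genes Prm1, Prm2 and Tnp2. These stood at 1.40, 0.741 and 0.874 FPKM in KIT and at 1.46, 0.584 and 0.780 FPKM in THY1 cells. Ldhc, the germ cell lactate dehydrogenase gene, stood at 31.9 FPKM in KIT and 1409 FPKM in THY1 cells, Crisp2 of the sperm acrosome at 7.58 against 334 FPKM, and Meig1, needed for spermatid shaping, at 36.9 against 978 FPKM. Of 23 late genes 13 were at least 4-fold lower in KIT cells (median -3.17, percentile 0), and the piRNA list was lower too (median -0.90, percentile 0.01), with Tdrd6 at 1.01 against 41.3 FPKM. In the self-renewal list 5 of 18 were at least 4-fold lower in KIT cells (median -1.43, percentile 0): Id4 stood at 2.85 against 49.1 FPKM, Ret at 1.23 against 21.3 FPKM and Gfra1 at 0.992 against 16.6 FPKM. Immediate early and heat shock genes were also lower (median -0.66, percentile 0.33).

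Genes of differentiating spermatogonia (median 1.37, percentile 100), the cell cycle (median 0.84, percentile 100) and meiotic prophase (median 0.64, percentile 100) were higher in P14 KIT cells. Stra8 stood at 251 against 35.0 FPKM, Prdm9 at 32.3 against 4.63 FPKM, Rhox13 at 99.0 against 23.6 FPKM and Dmc1, the meiotic recombinase gene, at 84.4 against 16.4 FPKM. DNA methylation genes were higher as a list (median 0.50, percentile 99.0), with the remodelling factor gene Hells at 1.65. The glucose transporter gene Slc2a3 stood at 10.4 against 364 FPKM and Ldha at 15.9 against 222 FPKM. Leydig markers were higher in KIT cells (median 1.27, percentile 100), while macrophage (median -2.27, percentile 0), peritubular myoid (median -1.72, percentile 0) and fibroblast markers (median -1.67, percentile 0) were lower. In all, 703 genes passed the size rule, 42 higher and 661 lower in KIT cells, and 295 at 8-fold, and 18 of 25 lists stood outside the central range.

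The comparison of P7 with P0 THY1 cells asks what changed in THY1-selected cells from birth to the first week. Progenitor and differentiation genes were higher at P7: 5 of 16 undifferentiated progenitor genes were at least 4-fold higher (median 0.93, percentile 100). The transcription factor genes Sox3 and Zbtb16 stood at 23.5 against 1.35 FPKM and 65.8 against 9.56 FPKM. The RNA-binding protein genes Nanos3 and Lin28a stood at 31.1 against 3.57 FPKM and 49.9 against 7.88 FPKM, and Stra8 at 39.7 against 1.35 FPKM. In the OCT4-GFP columns of these ages Sox3 stood at 55.5 against 6.28 FPKM, Lin28a at 117 against 79.3 FPKM and Stra8 at 88.2 against 21.4 FPKM. Transcripts of other cells, more abundant in P0 THY1, lower the share of germ cell transcripts there. How far this accounts for the rises in the THY1 columns was not tested. The differentiating (median 0.62, percentile 99.96), cell cycle (median 0.80, percentile 100), piRNA (median 0.55, percentile 99.8) and self-renewal lists (median 0.38, percentile 98.7) were also higher, and immediate early and heat shock genes were lower (median -0.80, percentile 0). In the OCT4-GFP columns the median level of the differentiating list was higher at P7 too (36.7 against 21.4 FPKM). There the cell cycle (73.7 against 82.6 FPKM), piRNA (55.6 against 63.5 FPKM) and self-renewal lists (15.5 against 34.7 FPKM) were lower at P7. Dnmt3l, the cofactor of germline DNA methylation, was lower at P7 (0.352 against 15.1 FPKM), and Tet1, a demethylation enzyme gene, stood at 0.789 against 6.15 FPKM. They were exceptions in the DNA methylation list, where 5 of 20 members were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.25 within the central range (percentile 93.0).

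Transcripts of fibroblasts, peritubular muscle-like cells and macrophages were lower at P7. Of 10 fibroblast and stroma markers 8 were at least 4-fold lower at P7 (median -3.96, percentile 0), with the matrix genes Lum at 1.49 against 171 FPKM, Postn at 6.68 against 306 FPKM and Col3a1 at 79.2 against 2307 FPKM. Peritubular myoid markers (7 of 8; median -2.69, percentile 0) and macrophage markers (8 of 12; median -2.67, percentile 0) were lower, and Sertoli markers were higher (median 0.51, percentile 99.7). Imprinted genes were also lower: 6 of 24 maternally expressed genes (median -0.71, percentile 0.02) and 7 of 29 paternally expressed genes (median -1.02, percentile 0) were at least 4-fold lower. H19 stood at 72.6 against 1013 FPKM, Igf2 at 14.5 against 203 FPKM, Dlk1 at 11.1 against 113 FPKM and Mest differed by -3.21. The size rule counted 707 genes, 69 higher and 638 lower at P7, and 13 of 25 lists stood outside the central range. With quantile normalization 150 were higher and 522 lower, and 417 remained when genes needed FPKM of 5 or more in 2 columns. In alternatives chosen after seeing the data, the count was 27 in the OCT4-GFP columns of the same ages (14 higher and 13 lower) and 1384 with the P7 VASA THY1 library in place of P7 THY1.

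From P7 to P12, THY1 cells had higher levels of meiotic and Sertoli cell transcripts and lower levels of cell cycle and self-renewal transcripts. Meiotic prophase genes were higher (14 of 35 by 2-fold or more; median 0.69, percentile 100), with Hfm1, a crossover helicase gene, at 19.2 against 3.37 FPKM and Spata22 at 12.9 against 1.56 FPKM. Sertoli markers were higher beside them (10 of 17 by 2-fold or more; median 1.43, percentile 100), with the tight junction gene Cldn11 at 152 against 27.7 FPKM, Gata1 at 14.3 against 1.59 FPKM and Tsx at 19.5 against 2.07 FPKM. Cell cycle genes were lower (median -0.72, percentile 0), with Plk1 (-1.38), Aurka (-1.17) and Cdc20 (-1.11), as were self-renewal genes (median -0.69, percentile 0), with Egr2 (-1.21), Pou3f1 (-1.17) and Id4 (-1.17). The fall of the cell cycle list did not last. Its median level in THY1 columns was 62.7, 36.0 and 61.5 FPKM at P7, P12 and P14. Peritubular myoid (median 0.87, percentile 99.94), macrophage (median 0.78, percentile 99.93) and fibroblast markers (median 0.45, percentile 99.5) were higher and endothelial markers lower (median -0.71, percentile 0). The red cell gene Alas2 stood at 0.572 against 83.7 FPKM and the spermatid gene Tnp1 at 3.60 against 55.0 FPKM, while the late meiotic and spermatid list had a median of 0.23 within the central range (percentile 87.5). By the size rule 137 genes differed, 97 higher and 40 lower at P12, and 11 of 25 lists stood outside the central range. With the P7 VASA THY1 library in place of P7 THY1 the count was 401 (378 higher and 23 lower), with 25 genes shared, and it was 211 with a pseudocount of 0.1.

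Across P0 to P12, THY1 cells showed higher progenitor (median 0.93, percentile 100), meiotic (median 0.88, percentile 100), piRNA (median 0.61, percentile 99.97) and Sertoli (median 1.83, percentile 100) transcripts. Lin28a stood at 79.6 against 7.88 FPKM (79.3 FPKM in P0 OCT4-GFP), Sycp3 at 229 against 42.8 FPKM and the Sertoli receptor gene Amhr2 at 102 against 7.65 FPKM. Fibroblast (median -3.26, percentile 0), macrophage (median -2.20, percentile 0) and both imprinted lists (maternally expressed -0.67, paternally expressed -0.95) were lower, with Meg3 at 4.20 against 44.8 FPKM. WNT (median -0.49, percentile 0.56) and FGF and BMP signalling genes (median -0.49, percentile 0.38) were lower, with Wnt5a at -3.38, Sfrp1 at -3.48 and Bmp4 at -2.71, and so were immediate early and heat shock genes (7 of 15 by 2-fold or more, percentile 0). HOX genes had a median of -0.63 within the central range (percentile 12.6). In all, 719 genes passed the size rule, 162 higher and 557 lower at P12. With quantile normalization 255 were higher and 540 lower. When genes needed FPKM of 5 or more in 2 columns, 453 remained, 152 higher and 301 lower. With P0 OCT4-GFP in place of P0 THY1, an alternative chosen after seeing the data, 723 genes were higher and 166 lower at P12, so the direction of the count depends on the P0 column. Median levels of some lists turned as well. In P12 THY1 against P0 OCT4-GFP, WNT genes stood at 8.76 against 3.57 FPKM and FGF and BMP genes at 9.40 against 5.38 FPKM. Maternally expressed imprinted genes stood at 19.6 against 11.3 FPKM and paternally expressed ones at 10.2 against 3.74 FPKM. Fibroblast and immediate early genes also stood higher, whereas the piRNA list was lower (40.2 against 63.5 FPKM). Macrophage markers stayed lower.

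From P7 to P12, KIT cells showed higher levels of meiotic genes. Of 35 meiotic prophase genes 15 were at least 4-fold higher at P12 and 26 at least 2-fold (median 1.82, percentile 100), with Hfm1 at 47.9 against 3.52 FPKM, the synaptonemal complex gene Sycp2 at 224 against 22.5 FPKM and Spata22 at 30.4 against 2.31 FPKM. Prdm9 stood at 31.5 against 3.11 FPKM, Mybl1, a regulator of meiotic piRNA genes, at 34.7 against 3.94 FPKM and the RNA-binding protein gene Ybx2 at 25.8 against 5.25 FPKM. Dmrtb1 was lower (5.84 against 42.7 FPKM), and cell cycle (median -0.38, percentile 1.20) and immediate early and heat shock genes (median -0.55, percentile 0.04) were lower as lists. Dmrtb1 and the cell cycle list were higher again in the 1 P14 KIT library, Dmrtb1 at 62.6 FPKM. The cell cycle list had median levels of 69.5, 62.1 and 76.5 FPKM in KIT columns at P7, P12 and P14. Leydig (8 of 12 by 2-fold or more; median -1.24, percentile 0) and endothelial markers (median -1.36, percentile 0) were lower and Sertoli markers higher (median 0.66, percentile 100), with Cyp17a1 at 38.7 against 245 FPKM and the renin gene Ren1 at 8.83 against 91.4 FPKM. The size rule counted 115 genes, 87 higher and 28 lower at P12, and 10 of 25 lists stood outside the central range.

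From P12 to P14, THY1 cells had higher levels of the late meiotic and spermatid list and lower levels of Sertoli transcripts. The spermatid genes Prm1, Prm2 and Tnp2 stayed low, at 1.46, 0.584 and 0.780 FPKM in P14 THY1. Of 23 late meiotic and spermatid genes 13 were at least 4-fold higher (median 3.84, percentile 100): Ldhc stood at 1409 against 4.54 FPKM, Crisp2 at 334 against 1.07 FPKM, Adam2, needed for sperm and egg binding, at 119.8 against 0.609 FPKM and Meig1 at 978 against 16.8 FPKM. The piRNA (median 1.15, percentile 100), meiotic prophase (median 0.77, percentile 99.99) and oxidative phosphorylation lists (median 0.80, percentile 99.8) were higher, with Tdrd6 at 41.3 against 0.370 FPKM and Ndufb5 at 1.56. Slc2a3 stood at 364 against 11.2 FPKM, whereas the glycolysis list that holds it had a median level of 13.7 against 22.1 FPKM. Of 17 Sertoli markers 14 were at least 4-fold lower (median -3.96, percentile 0), with Cldn11 at 2.70 against 152 FPKM and Clu at 24.8 against 900.0 FPKM, while fibroblast markers were higher (median 1.08, percentile 99.7). The stress genes Atf3 (-4.50) and Ier3 (-3.56) were lower with their list (median -0.96, percentile 0.01). By the size rule 1281 genes differed, 699 higher and 582 lower at P14, and 541 at 8-fold (361 higher and 180 lower).

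The same step in KIT cells, a comparison chosen after seeing the data, gave 329 genes, 27 higher and 302 lower at P14. Self-renewal genes were lower (median -1.32, percentile 0), with Gfra1 at 0.992 against 12.3 FPKM, as were progenitor genes (median -0.84, percentile 0), with Nanos3 at -1.74, and pluripotency genes (median -0.50, percentile 2.08), with the orphan receptor gene Nr0b1 at -2.67. Late genes (median 0.58, percentile 100), with Ldhc at 31.9 against 1.88 FPKM, and oxidative phosphorylation genes (median 0.90, percentile 100) were higher. Immediate early and heat shock genes (median -0.56, percentile 0.67) and Sertoli markers (median -2.63, percentile 0) were lower here too, with Wt1 at 2.08 against 36.4 FPKM, and Leydig markers were higher (median 0.89, percentile 100).

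**Figure D2:**
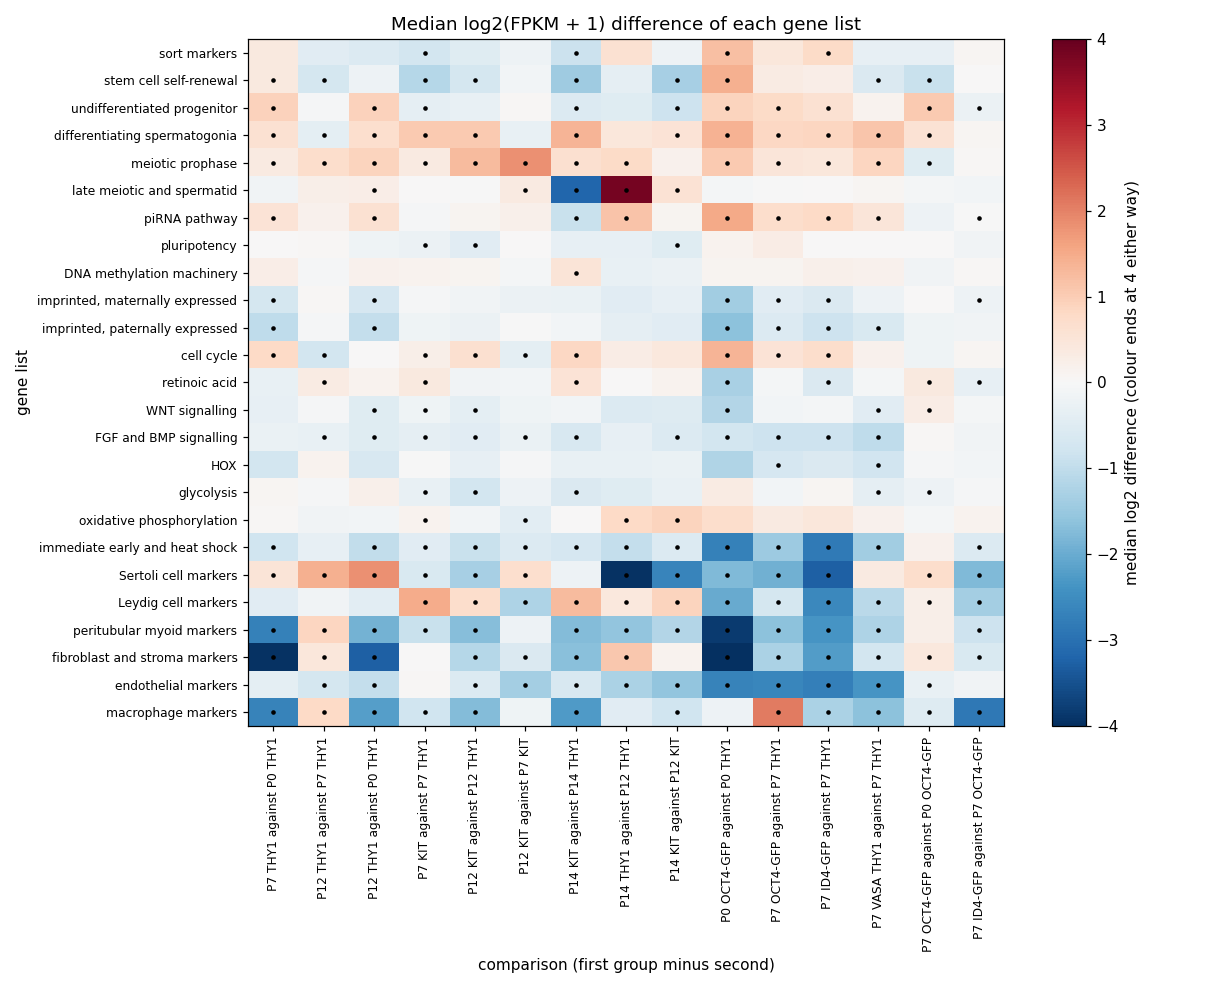
Median log2(FPKM + 1) difference of each gene list (vertical axis) in 15 comparisons (horizontal axis), first group minus second, red higher and blue lower, with the colour ending at 4 in either direction. Dots mark medians outside the central 95% of random lists. The late meiotic and spermatid list is at 3.84 in P14 against P12 THY1 cells and at -3.17 in P14 KIT against THY1 cells.

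At P0, OCT4-GFP cells held more germ cell transcripts and far fewer transcripts of most other testis cells than THY1 cells. Marker, mouse line and sorting method differ together in this comparison, so their effects cannot be told apart. Gfra1 stood at 153 against 20.4 FPKM, Ret at 106 against 22.3 FPKM, the GDNF-responsive gene Bcl6b at 62.6 against 9.86 FPKM, Lin28a at 79.3 against 7.88 FPKM and Ddx4 at 241 against 65.0 FPKM. The self-renewal (12 of 18 by 2-fold or more; median 1.43, percentile 100), piRNA (median 1.53, percentile 100), differentiating (median 1.39, percentile 100), cell cycle (median 1.34, percentile 100) and meiotic prophase lists (median 1.05, percentile 100) were higher. Fibroblast (median -6.17, percentile 0), peritubular myoid (median -3.81, percentile 0), endothelial (median -2.67, percentile 0), Leydig (median -2.03, percentile 0) and Sertoli markers (median -1.77, percentile 0) were lower, with Col1a1 at 8.59 against 1132 FPKM, while macrophage markers had a median of -0.22 within the central range. Imprinted genes were also lower (maternally expressed -1.40, paternally expressed -1.64), Plagl1 at 1.55 against 52.8 FPKM and Grb10 at 19.3 against 217 FPKM. Immediate early genes were lower (median -2.69, percentile 0), with Jun at 7.29 against 134 FPKM and Fos at 55.8 against 738 FPKM. In all, 1322 genes passed the size rule, 151 higher and 1171 lower in OCT4-GFP cells, 388 and 948 with quantile normalization, and 519 in all at 8-fold.

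At P7, OCT4-GFP cells differed from THY1 cells in progenitor and macrophage genes. As at P0, marker, mouse line and sorting method differ together, so their effects cannot be told apart. Neurog3, of committed progenitors, stood at 14.0 against 0.843 FPKM, and the progenitor (median 0.76, percentile 99.96), differentiating (median 0.82, percentile 99.98) and piRNA lists (median 0.70, percentile 99.98) were higher. Macrophage markers were higher (7 of 12 by 4-fold or more; median 2.08, percentile 100), with the complement gene C1qa at 40.5 against 4.15 FPKM and Mrc1 at 21.4 against 1.83 FPKM, whereas Cd74, also on that list, stood at 1.07 against 32.2 FPKM. Endothelial (median -2.62, percentile 0) and Sertoli markers (median -1.93, percentile 0) were lower, with Emcn at 0.217 against 31.4 FPKM and Kitl at 3.17 against 42.7 FPKM, and HOX (median -0.68, percentile 0.72) and immediate early genes (median -1.46, percentile 0) were lower as lists. FGF and BMP signalling genes were lower (median -0.83, percentile 0.01), with Id2 at -3.92 and Id3 at -3.48, and the growth regulator gene Myc stood at 0.506 against 21.8 FPKM. The size rule counted 457 genes, 34 higher and 423 lower in OCT4-GFP cells. The count was 166 against P7 VASA THY1 in place of P7 THY1 (52 higher and 114 lower) and 154 at 8-fold.

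ID4-GFP cells at P7 had the lowest median levels of Sertoli, Leydig, peritubular myoid and fibroblast markers of the 11 columns. Against P7 THY1, marker, mouse line and sorting method again differ together and cannot be told apart. Sertoli (13 of 17 by 4-fold or more; median -3.26, percentile 0), Leydig (median -2.57, percentile 0), endothelial (median -2.74, percentile 0), fibroblast (median -2.23, percentile 0) and immediate early genes (median -2.84, percentile 0) were lower than in THY1 cells. Clu stood at 7.24 against 414 FPKM, Cyp11a1 at 0.338 against 36.8 FPKM, Sparc at 3.10 against 307 FPKM and Atf3 at 0.664 against 42.8 FPKM. The differentiating (median 0.86, percentile 99.99) and piRNA lists (median 0.79, percentile 99.99) were higher, with Ccnd1 (1.75), Uhrf1 (1.75) and the piRNA nuclease gene Pld6 (2.43), and Neurog3 stood at 7.30 against 0.843 FPKM. The self-renewal list had a median of 0.28 within the central range (percentile 78.5), Id4 itself differing by -0.09. By the size rule 666 genes differed, 17 higher and 649 lower in ID4-GFP cells, 293 against P7 VASA THY1 in place of P7 THY1 and 310 at 8-fold. Rmrp, a structural RNA with 21.6% to 41.0% of the summed FPKM in the other 10 columns, was listed at 0 in ID4-GFP.

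Against OCT4-GFP cells of the same age, a comparison chosen after seeing the data, ID4-GFP cells had 66 genes lower and 0 higher, 25 at 8-fold. Macrophage (median -2.85, percentile 0), Sertoli (median -1.75, percentile 0) and Leydig markers (median -1.35, percentile 0) were lower, with C1qa at 1.21 against 40.5 FPKM and Lyz2 at 3.19 against 68.0 FPKM. Immediate early and heat shock genes had a median level of 9.77 against 15.4 FPKM. The self-renewal (median 0.01), differentiating (0.08) and meiotic prophase lists (0.04) lay within the central range, and progenitor genes were lower as a list (median -0.22, percentile 0), with Upp1 at -1.42 and Ddit4 at -1.06.

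The P7 VASA THY1 library held more transcripts of differentiating and meiotic germ cells than P7 THY1 (differentiating list median 1.10, percentile 100; meiotic prophase list median 0.86, percentile 100). Dmrtb1 stood at 41.2 against 5.49 FPKM, Prdm9 at 7.27 against 1.45 FPKM and Mei1 at 13.9 against 3.33 FPKM. Self-renewal genes were lower (median -0.57, percentile 0.26), with Spry4 at 2.72 against 21.6 FPKM and the chemokine receptor gene Cxcr4 at 4.41 against 26.2 FPKM, and immediate early and heat shock genes had a larger difference (median -1.39, percentile 0). Endothelial (median -2.35, percentile 0), macrophage (median -1.64, percentile 0) and Leydig markers (median -1.09, percentile 0) were lower, with Cd74 at 0.567 against 32.2 FPKM, and Sertoli markers had a median of 0.35 within the central range (percentile 95.1). In all, 363 genes passed the size rule, 43 higher and 320 lower than in P7 THY1, and 133 at 8-fold. Selection, mouse line and sorting method may differ together here too, and effects of these cannot be told apart.

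Between P0 and P7, OCT4-GFP cells differed in 27 genes, the fewest of the 55 pairs of columns, in a comparison chosen after seeing the data: 14 were higher and 13 lower, 54 in all with a pseudocount of 0.1 and 5 at 8-fold. Progenitor genes were higher at P7 (median 1.05, percentile 100), with Neurog3 at 14.0 against 0.607 FPKM, Sox3 at 55.5 against 6.28 FPKM and the retinoic acid receptor gene Rarg at 19.6 against 3.63 FPKM. Kit stood at 36.7 against 7.79 FPKM and Stra8 at 88.2 against 21.4 FPKM. Self-renewal genes were lower (8 of 18 by 2-fold or more; median -0.90, percentile 0), with Gfra1 at 58.7 against 153 FPKM and Bcl6b at 20.4 against 62.6 FPKM, and meiotic prophase genes were lower (median -0.48, percentile 0), with Tex15 at -1.39 and Hormad1 at -1.31. Of the markers of other cells, Sertoli (median 0.71, percentile 100) and fibroblast markers (median 0.41, percentile 99.7) were higher and macrophage markers lower (median -0.50, percentile 0.05). The median differences of the imprinted lists lay within the central range (maternally expressed 0.01, paternally expressed -0.19).

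**Figure D3:**
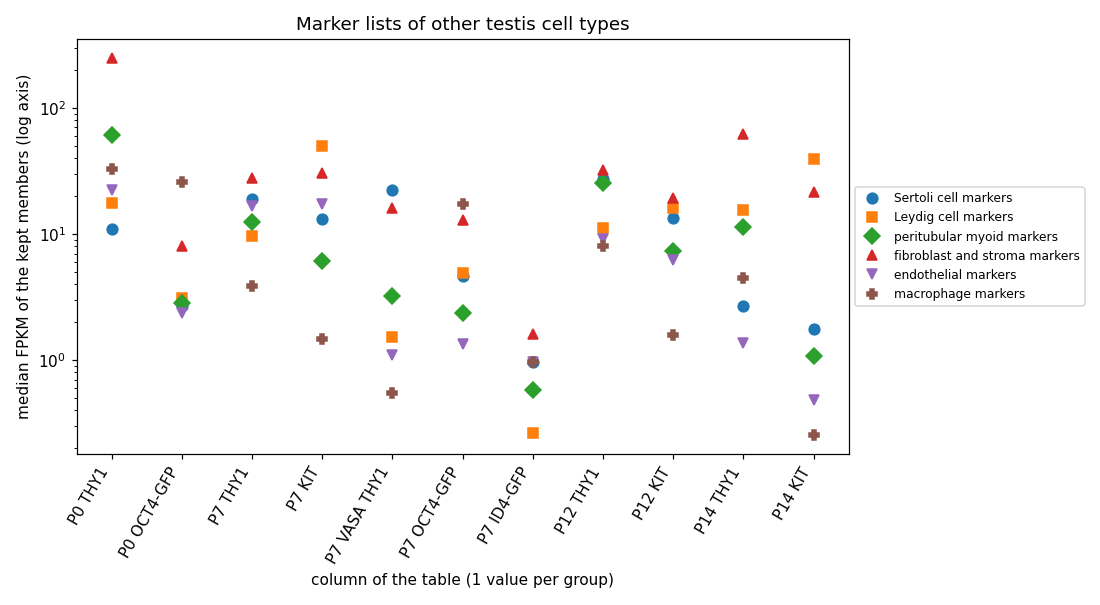
Median FPKM (vertical axis, log scale) of the kept members of 6 marker lists of other testis cell types in the 11 columns (horizontal axis), 1 point per list and column. Fibroblast markers reach 249 FPKM in P0 THY1, Leydig markers reach 49.9 FPKM in P7 KIT, and Sertoli markers stand at 27.4 FPKM in P12 THY1 and 2.70 FPKM in P14 THY1.

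Imprinting is in the title of the series, and 10 of 12 imprinted genes fixed in advance had their highest level in P0 THY1. H19 stood at 1013 FPKM in P0 THY1, 80.6 FPKM in P0 OCT4-GFP and between 12.5 and 72.6 FPKM in the other 9 columns. Igf2 stood at 203 FPKM in P0 THY1 and 8.81 FPKM in P0 OCT4-GFP, and Peg3 at 146 and 9.93 FPKM. In P7 ID4-GFP, Meg3 stood at 1.89 FPKM, Plagl1 at 0.682 FPKM, Kcnq1ot1 at 1.44 FPKM, Cdkn1c at 29.9 FPKM and Igf2r at 40.4 FPKM, against 10.3, 13.9, 9.65, 32.7 and 44.3 FPKM in P7 THY1, while Mest differed by 0.21.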

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

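The tests of explanations in this part were chosen after the results were seen. Some list medians went opposite ways in parallel comparisons, and the differences between comparisons were not tested between samples, since each group had 1 value. From P0 to P7 the self-renewal list had a median of 0.38 in THY1 columns and -0.90 in OCT4-GFP columns, a difference of 1.28. The meiotic prophase list had 0.37 and -0.48, a difference of 0.85. The fibroblast list had -3.96 and 0.41, a difference of -4.37, and from P7 to P12 it had 0.45 in THY1 and -0.57 in KIT columns, a difference of 1.02 between medians. Only this last one was set against random lists, as the change of the KIT minus THY1 difference from P7 to P12, with a median over genes of -1.10 and percentile 0. Under the size rule 3 genes also went opposite ways, each listed at 0 in a compared column, and were left out for that reason, a choice made after their values were seen. The only named gene among them, Celf2, was listed at 0 in P7 KIT and P12 THY1, against 18.1 FPKM in P12 KIT.

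The first pattern is the 638 genes at least 4-fold lower in P7 THY1 than in P0 THY1. A change with age within OCT4-GFP germ cells would need P0 THY1 levels in P0 OCT4-GFP. There the genes differed from P0 THY1 by a median of -2.85 (quartiles -3.78 and -1.92). The same P0 THY1 value selected these genes and enters this difference, so a lower level was partly set in advance. No conclusion is drawn from it. The OCT4-GFP columns played no part in the selection. Of the 158 at 5 FPKM or more in P0 OCT4-GFP, 27.2% were at least 2-fold lower in P7 OCT4-GFP, and for these a smaller change stays open. At the 4-fold rule of the pattern, 13 genes in all were lower in P7 than in P0 OCT4-GFP. Most of the 638 thus did not pass that rule there, and genes under 5 FPKM in P0 OCT4-GFP could not. A lower germ cell share at P0 with other cell types in constant proportion would raise all their markers alike, but Sertoli markers were higher at P7 (median 0.51, quartiles 0.17 and 1.32) while fibroblast markers were lower (quartiles -4.79 and -3.05). More fibroblast, peritubular and macrophage RNA in the P0 THY1 value and a change with age in THY1 cells that OCT4-GFP cells do not share cannot be told apart: the 23 of 30 members of these marker lists at least 4-fold lower at P7 raised the first explanation and do not test it.

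The second pattern is the 699 genes at least 4-fold higher in P14 THY1 than in P12 THY1. Only 16.5% of them were at least 2-fold higher in P14 than in P12 KIT, which argues against an age change shared by both selections as the cause of most, and a higher germ cell share with stages in constant proportion would raise the progenitor list as well, which had a median of -0.49 within the central range (percentile 5.14, quartiles -0.80 and -0.25). The median FPKM of the 699 genes was 33.1 in P14 THY1 and 3.25 in P14 KIT. RNA of later germ cells in the 1 P14 THY1 library and a biological difference of THY1 cells at P14 cannot be told apart: the 13 of 23 members of the late meiotic and spermatid list at least 4-fold higher, with Ldhc at 1409 FPKM, raised the first explanation and do not test it, and 1 library gives no check.

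The third pattern is the Leydig genes higher in P7 KIT than in P7 THY1. A lower germ cell share in the KIT value with other cell types in constant proportion would raise Sertoli markers as well. These were lower (median -0.60, quartiles -0.78 and -0.48) while the Leydig quartiles were 0.68 and 3.30. A lower germ cell share made up by Leydig cells alone is not addressed by these values. RNA of Leydig cells, which also carry KIT, and a biological difference of KIT-positive germ cells in these genes cannot be told apart: the 8 of 12 Leydig list members at least 2-fold higher, with Hsd3b1 at 324 and Insl3 at 258 FPKM, are the pattern itself and test neither.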

How the results depend on the processing

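Within an age no paired analysis was possible because the columns carry no replicate numbers. Across ages the KIT and THY1 columns form 3 pairs, and a test of the marker on these was possible but left out, as the marker was compared at each age. For lack of replicates the planned limma alternatives (without trend, robust, the contrast alone, a replicate block, pooled spread for lone libraries, adjusted p with 2-fold), leaving out single replicates and camera with an estimated correlation were not run. The minimum of 1 FPKM in 2 columns played no part in the size rule, so lifting it was no test and was not run. Leaving out the rule's own minimum of 5 FPKM in the higher column kept every total count within 1.5 times. That alternative, exchanging columns and leaving out genes listed at 0 were chosen after seeing the data. In the planned comparisons no list median outside the central range reversed with a pseudocount of 0.1 or quantile normalization. None of 310 differences reversed either, those of the genes named for the largest differences in each direction. Genes named for other reasons and list medians of the comparisons added afterwards were not part of this check. Quantile normalization and upper-quartile scaling kept every total count within 1.5 times, though not the higher and lower counts taken apart. Of 325 list medians 316 kept their side of the central range with a pseudocount of 0.1 and 307 with quantile normalization. Quantile normalization moved the all-gene median by 0.21 for P7 against P0 THY1, 0.14 for P12 against P0 THY1, 0.11 for P14 KIT against THY1, 0.13 for P14 against P12 KIT and 0.24 for P0 OCT4-GFP against THY1 (-0.10 with upper-quartile scaling). Under quantile normalization P7 against P0 THY1 had 150 genes higher and 522 lower, and P12 against P0 THY1 had 255 higher and 540 lower. P0 OCT4-GFP against THY1 had 388 higher and 948 lower.

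The majority direction of some counts turned. P12 against P0 THY1 had 162 genes higher and 557 lower, but 723 higher and 166 lower with P0 OCT4-GFP in place of P0 THY1, with 202 shared. P14 against P12 THY1 had 699 higher and 582 lower, but 27 higher and 302 lower in KIT columns. With the stricter minimum it had 346 higher and 540 lower, which by construction leaves out genes at 5 FPKM or more in P14 THY1 alone and says nothing on direction. P7 KIT against THY1 had 31 higher and 44 lower, but 205 higher and 43 lower with P7 VASA THY1, with 32 shared. P7 against P0 had 69 higher and 638 lower in THY1 columns, but 14 higher and 13 lower in OCT4-GFP columns, where a pseudocount of 0.1 gave 21 higher and 33 lower and leaving out the minimum gave 14 and 15.

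Counts moved as follows, and apart from stricter rules, which leave fewer genes by construction, the cause was not tested. With 8-fold the counts were 519 for P0 OCT4-GFP against THY1, 72 for P14 against P12 KIT, 295 for P14 KIT against THY1, 541 for P14 against P12 THY1, 25 for ID4-GFP against OCT4-GFP, 310 for ID4-GFP, 154 for OCT4-GFP and 133 for VASA THY1 against P7 THY1, and 5 for OCT4-GFP with age. With the stricter minimum they were 453 for P12 against P0 THY1, 363 for P14 KIT against THY1 and 417 for P7 against P0 THY1. With a pseudocount of 0.1 they were 160 for the change of the KIT to THY1 contrast, 92 for P12 KIT against THY1, 211 for P12 against P7 THY1 and 54 for OCT4-GFP with age. With P7 VASA THY1 in place of P7 THY1 they were 652 for the change of contrast, 401 for P12 against P7 THY1, 293 for ID4-GFP, 248 for P7 KIT, 166 for OCT4-GFP and 1384 for P7 against P0 THY1. OCT4-GFP columns gave 27 for P7 against P0, with 6 genes shared with the THY1 count, and KIT columns gave 329 for P14 against P12, with 255 shared. Without counts of fragments, depth limits low values by an unknown amount.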

Other observations

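Histone genes differed between columns as a group. Over 57 expressed histone genes, a set chosen after seeing the data, the median level was 146 FPKM in P7 OCT4-GFP, 134 FPKM in P14 KIT and 123 FPKM in P7 ID4-GFP, and 34.4 FPKM in P12 THY1. The median difference was 1.02 from P0 to P7 in OCT4-GFP, 1.45 from P12 to P14 in KIT and -1.23 from P0 to P12 in THY1 columns. Histone genes form a multigene family whose members could share reads, so single members are uncertain. The histone variant gene H2afx, counted from P12 to P14 in KIT columns, no longer passed the size rule under quantile normalization, with 1.51.

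Among the 11 columns, 4 sperm chromatin genes and 2 red cell genes were highest in P7 THY1. Prm1, Prm2, Tnp1 and Tnp2 stood at 101, 29.7, 55.0 and 37.7 FPKM there, while Prm1 stood at 1.46 FPKM in P14 THY1. The haem enzyme gene Alas2 stood at 83.7 FPKM and the globin gene Hbb-b2, which could share reads with its copy, at 886 FPKM, against 6.72 and 31.2 FPKM in P0 THY1. The mast cell genes Cma1 and Mcpt4 and the neutrophil gene S100a8 were highest in P0 THY1 and next in P7 THY1, Cma1 at 99.3 and 33.5 FPKM, Mcpt4 at 59.1 and 34.9 FPKM and S100a8 at 314 and 93.1 FPKM. The T cell genes Cd3g and Cd2 stood at 6.78 and 5.68 FPKM in P0 THY1, and the T cell and red cell lists had 4 kept members each, too few for a percentile. The macrophage gene C1qa was present in both OCT4-GFP columns (62.3 FPKM at P0 and 40.5 FPKM at P7) and in P0 THY1 (67.2 FPKM), and Hoxa4 stood at 14.7 FPKM in P14 THY1 and at 0.768 FPKM in P14 KIT.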
